A study of Homo sapiens with 6 samples.

How the data were processed

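RNA abundance was measured in 6 libraries from MCF7, an established line of human estrogen receptor positive breast cancer cells. Of these, 3 came from cells expressing non-silencing control shRNAs (control shRNA) and 3 from cells expressing shRNAs against LIFR, the leukemia inhibitory factor receptor (LIFR shRNA). A short hairpin RNA is processed in the cell into a small RNA that lowers the transcript it matches. The labels call the 3 libraries of a group biological replicates, each from an independent experiment in standard plastic culture. Cells were grown in medium with 10% serum and were moved 16 h before harvest to medium with 2% serum and a small volume of buffer, per the labels' protocols. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit (KAPA), per the labels' protocols. How many hairpins or independently transduced cell populations stand behind each group is not given in the sources used here.

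The authors deposited raw read counts per gene and library, which are whole numbers with no normalization. STAR 2.5.2a, HTSeq, DESeq and edgeR, and the builds hg38 and GRCh38, are named in the submitters' processing notes without a role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands, such as LIFR and LIFR-AS1, may not have been told apart. Reads of genes that share exons, such as the UGT1A genes, could also be split or dropped by the counting. The authors' deposited table of the same comparison gives log2 fold changes from DESeq2 and edgeR, per the file headers. It also gives p-values from both tools, per the file headers. The baySeq columns hold 1 minus a likelihood, raw and adjusted, a score read from the deposited table and counted as passing under 0.05. The deposited ranks of genes by each tool are a score that entered no result.

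The count table held 46783 genes. Library totals were 33045070, 34277878 and 30252573 counts for control replicates 1 to 3 and 31863618, 36459410 and 48310181 for LIFR shRNA replicates 1 to 3. At these totals LIFR itself was covered by 538 to 1112 counts per library. Intervals from the fit cover the spread between these 3 and 3 libraries. Counting error is included in them, and any difference between the cell populations that was present in all 3 experiments is not.

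The counts as deposited were fitted with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr over the 2 groups with a minimum count of 10 and a minimum total of 15, which left 17608 genes. Libraries were scaled by TMM factors, which lay between 0.9925 and 1.0091. LIFR shRNA was compared with control shRNA by the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest), with no covariate and Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values were computed by edgeR from the counts and the TMM-scaled library totals, and levels are given as mean ± SD over 3 libraries. A single gene was also tested by an exact 2-sided permutation of the 6 libraries, which has 10 distinct splits and cannot go below p = 0.1.

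Before the data were examined, 23 gene lists, the tests and all alternatives but the pair named below were fixed. Lists with at least 5 tested genes (22 of them) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera compares a list with the other genes. The calls were repeated with a correlation estimated from the data. In that setting camera takes its degrees of freedom from the libraries and not from the number of genes. The fry test, which asks whether the genes of a list move on balance in 1 direction, or in either direction, was run beside it. Genes named in the text follow a rule fixed at the same time. It takes LIFR and the tested gp130 list, the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of 2 or more, a gene symbol not taken from a clone or accession, and no overlap between groups. It also takes up to 4 rising and 4 falling members of each list with the smallest adjusted p, or the 2 most abundant members where none passed, and the 3 most abundant genes changed at least 2-fold in each direction. Genes outside this rule are marked as chosen after their values were seen.

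Positions were taken from GENCODE 29 on GRCh38 by gene identifier, which matched 99.2% of the genes tested. Libraries of a group were compared for duplicates by a chi-square test of their counts over genes with at least 20 counts in the pair. The statistic per gene was between 2.22 and 4.50 within groups and between 13.1 and 21.2 across groups, so no library was within sampling noise of another. For the median gene it was 1.28 to 1.72 times its expectation within groups and 3.73 to 5.18 times across groups. The typical gene thus varied little beyond counting error between replicates. The biological coefficient of variation, the spread beyond counting error, was 2.56%, so small changes could be called. The first principal component of log2 CPM held 55.4% of the variance and separated the groups.

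The alternatives were DESeq2 1.42.0, DESeq2 size factors inside edgeR, library totals alone, upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, limma-voom, non-robust estimation, an adjusted p under 0.01, glmTreat against a 1.5-fold change, and leaving out each library in turn. For lists they were an estimated correlation, a prior count of 0.5, and leaving out members shared between lists. After the data were seen, libraries thinned to the smallest total and the removal of each library's trends over GC content and transcript length were added. The scripts were tested on simulated counts for LIFR shRNA against control shRNA, with 17333 genes tested. Of genes changed 1.2-fold, 50% were recovered, with 56.3% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and unchanged genes made up 7.6% of the simulated calls. Only 48 to 50 tested genes were changed per fold, whereas 32.3% of genes were called in the data. These shares therefore need not hold for the real comparison.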

Results

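The transcriptome of MCF7 breast cancer cells was measured in 6 RNA-seq libraries. In 3 of them the cells carried control shRNA, and in 3 they carried shRNA against LIFR, the receptor chain that pairs with gp130 (IL6ST) to bind leukemia inhibitory factor and related cytokines. Totals ranged from 30252573 to 48310181 counts per library, and 28230 to 30588 genes had at least 1 count. Transcripts of the mitochondrial genome took 3.69 to 4.60% of counts, and the 10 most abundant genes took 4.66 to 5.30%. The comparison asked which transcripts differed when LIFR was depleted in cells kept in 2% serum for 16 h before harvest.

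LIFR (ENSG00000113594, minus strand of chromosome 5, 38474963 to 38608354 on GRCh38) was lower in every library with LIFR shRNA. Its level was 33.5 ± 1.57 CPM (SD, n = 3) with control shRNA and 17.0 ± 0.163 CPM (SD, n = 3) with LIFR shRNA, which is 50.8% of control. The counts were 1083, 1112 and 1077 in control replicates 1 to 3, and 538, 617 and 825 in LIFR shRNA replicates 1 to 3. The log2 fold change was -0.97 with a standard error of 0.047 and an edgeR adjusted p of 2.47e-19. The exact 2-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. LIFR-AS1, named after its values were seen because it overlaps LIFR on the opposite strand, was counted at 4.54 ± 0.657 CPM with control shRNA and 3.99 ± 0.0695 CPM with LIFR shRNA (SD, n = 3, edgeR adjusted p = 0.203).

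Receptor chains and ligands of the gp130 family were mostly lower along with the target. Of 13 tested members, LIFR included, 8 fell, 1 rose and 4 did not pass the test (adjusted over the list alone, 9 fell and 1 rose). OSMR, the oncostatin M receptor chain, lies near LIFR on chromosome 5 and fell from 107.5 ± 0.289 to 72.5 ± 2.16 CPM (SD, n = 3, 1.48-fold lower). IL27RA fell 1.77-fold, IL6R 1.74-fold and the secreted cytokine receptor CRLF1 1.5-fold. LIF, the ligand of LIFR, fell from 4.31 ± 0.438 to 2.26 ± 0.178 CPM (1.89-fold lower). The shared signalling chain IL6ST rose, from 64.2 ± 1.04 to 73.8 ± 1.69 CPM (1.15-fold). CNTFR (log2 fold change -0.76, adjusted p = 0.0634), CLCF1 (-0.19, adjusted p = 0.126), CNTF (0.38, adjusted p = 0.494) and IL11RA (0.07, adjusted p = 0.839) did not pass. The list was lower than other genes by camera (median log2 fold change -0.57, adjusted p = 0.000561, or adjusted p = 0.117 with an estimated correlation). The calls of the low-abundance ligands IL11 (-0.42, adjusted p = 0.0143) and CTF1 (-0.39, adjusted p = 0.0391) were fragile: IL11 did not pass without control replicate 1 (adjusted p = 0.0721), control replicate 3 (0.0583) or LIFR shRNA replicate 3 (0.0552), or by DESeq2 (0.109), and CTF1 did not pass without control replicate 1 (0.334) or LIFR shRNA replicates 1, 2 or 3 (0.0846, 0.0754 and 0.0658), by DESeq2 (0.188), by limma-voom (0.0682), with no filter on low counts (0.0525) or after GC content and length trends were removed (0.103). CNTFR did pass without control replicate 2 (adjusted p = 0.0295) or LIFR shRNA replicate 2 (0.047), or after thinning to the smallest library total (0.0461).

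**Figure D1:**
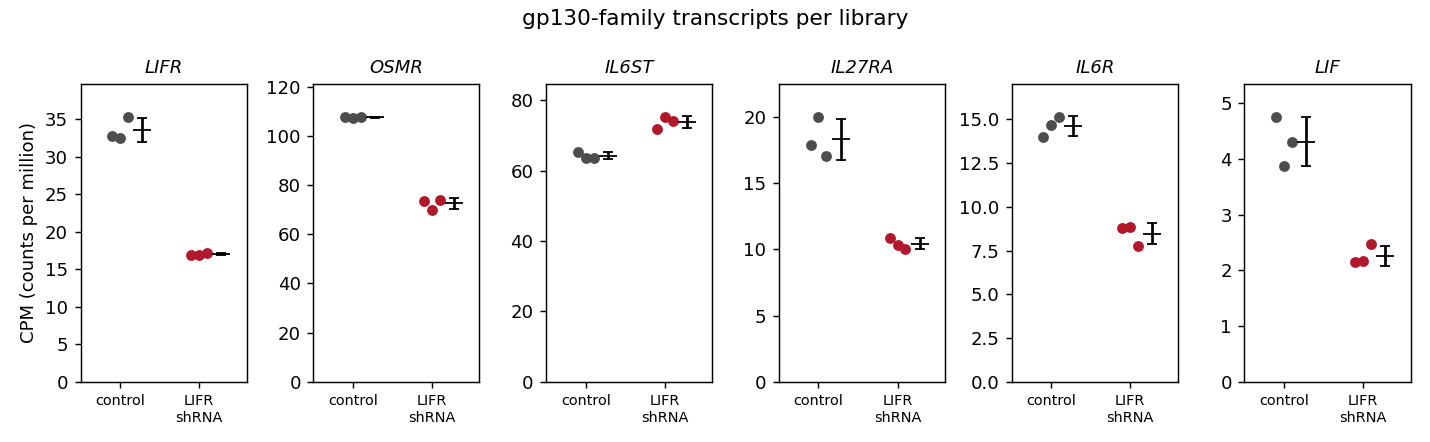
Transcript levels of 6 gp130-family genes in CPM (y axis, from 0 in each panel), in the 3 control shRNA libraries (grey points) and the 3 LIFR shRNA libraries (red points), with the mean ± SD beside them in black. LIFR lay between 16.9 and 17.2 CPM with LIFR shRNA and between 32.4 and 35.3 CPM in controls, and IL6ST is the only gene of the 6 plotted that was higher with LIFR shRNA.

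Across the transcriptome 5687 of 17608 tested genes changed (32.3%), with 2857 higher and 2830 lower with LIFR shRNA. Most changes were small: 4648 of the changed genes (81.7%) differed by less than 1.5-fold, and 373 differed by at least 2-fold, of which 159 were higher and 214 lower. Among called genes with a mean log2 CPM of 2 or more, the largest rise was that of ADGRL2 (chromosome 1, 81306160 to 81992436), an adhesion G protein-coupled receptor of the latrophilin family, from 2.91 ± 0.382 to 17.8 ± 0.506 CPM (6.14-fold). LUM, which encodes the matrix proteoglycan lumican (chromosome 12, 91102629 to 91111831), rose 5.34-fold from 1.19 ± 0.168 CPM. The sodium-calcium exchanger SLC8A1 rose 3.53-fold, the membrane-bound metalloproteinase MMP16 3.48-fold, the ubiquitin-conjugating enzyme UBE2E2 3.34-fold, the actin-severing protein SCIN 3.27-fold and FAM65C 3.05-fold. TFPI, an inhibitor of tissue factor coagulation, rose from 35.7 ± 0.340 to 104 ± 2.11 CPM (2.91-fold), and GPC6, EML5, SLC6A14 and CLIC3 rose 2.78-, 2.75-, 2.72- and 2.70-fold. Among abundant genes the mannosidase MAN1A1 rose 2.06-fold and the calcium-binding protein S100A16 2.51-fold.

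The largest falls under the same limit were in DMD, which encodes dystrophin (chromosome X, 31097677 to 33339441), at 5.15-fold lower, and in the neural transcription factor ASCL1 (chromosome 12, 102957686 to 102960516), which fell from 22.8 ± 0.956 to 4.41 ± 0.619 CPM (5.09-fold lower). COL3A1, the chain of type III collagen (chromosome 2, 188974320 to 189012746), fell from 294.4 ± 10.5 to 61.5 ± 0.971 CPM (4.79-fold lower), the smallest adjusted p of all genes tested (4.45e-38). AMPH fell 4.30-fold, the oxytocin receptor OXTR 3.72-fold, TMTC1 3.65-fold, the ETS factors ETV4 and ETV5 3.25- and 2.86-fold, and PLEKHA4 2.88-fold. The EGF receptor ligand AREG fell from 67.5 ± 7.74 to 24.7 ± 0.592 CPM (2.75-fold lower). MMP24-AS1 (3.13-fold lower) overlaps MMP24 on the opposite strand and UGT1A6 (2.74-fold lower) shares exons with other UGT1A genes, so which gene their reads came from is uncertain. BMP7, a bone morphogenetic protein, was the most abundant gene that changed at least 2-fold, and fell from 554 ± 22.9 to 223 ± 6.90 CPM (2.48-fold lower). Each of these largest changes had an adjusted p of 0.000123 or less by the edgeR quasi-likelihood test, and none lost its call in an alternative that tested it. DESeq2 called fewer genes higher than edgeR, 1902 against 2857, and 201 genes changed at least 2-fold when at least 1 CPM was required in 3 libraries.

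**Figure D2:**
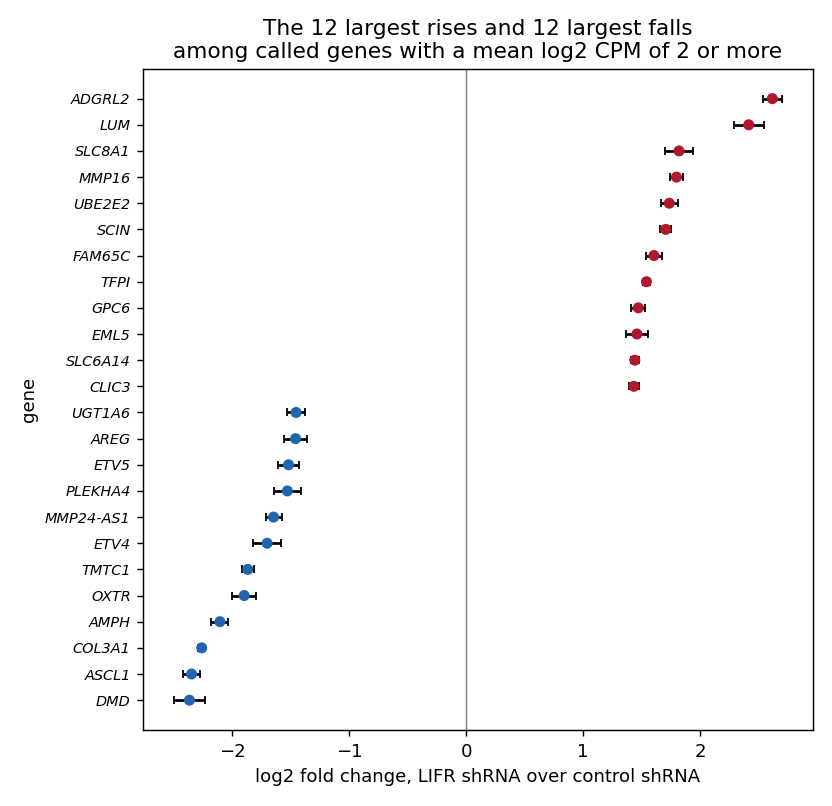
Log2 fold change of LIFR shRNA over control shRNA (x axis) for the 12 genes with the largest rise (red) and the 12 with the largest fall (blue) among called genes with a mean log2 CPM of 2 or more, 1 gene per row, with bars of 1 standard error from the edgeR fit of 3 against 3 libraries. Of the genes plotted, ADGRL2 stands highest at 2.62 and DMD lowest at -2.37.

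Immediate early genes and feedback regulators of the ERK pathway were lower as a group. Of 27 tested members 19 fell and 2 rose, with the same counts adjusted over the list alone. ETV5 and ETV4, transcription factors induced by ERK signalling, fell by 1.52 and 1.70 on the log2 scale. EGR3 fell from 47.9 ± 4.30 to 24.8 ± 0.531 CPM, and the ERK phosphatase DUSP4 from 97.4 ± 6.79 to 57.9 ± 1.57 CPM (SD, n = 3). EGR1, chosen after its values were seen, fell from 75.1 ± 7.46 to 29.8 ± 1.10 CPM. MYC and IER3 went the other way, at 1.15- and 1.1-fold higher. The list was lower than other genes by camera (median log2 fold change -0.26, adjusted p = 1.11e-06, or adjusted p = 0.181 with an estimated correlation).

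Among 32 targets and feedback genes of STAT3, the transcription factor activated downstream of gp130, 18 fell and 6 rose (18 and 7 adjusted over the list alone). The anti-apoptotic gene BCL2 fell 1.72-fold, the interleukin 4 receptor IL4R 1.57-fold, the metalloproteinase inhibitor TIMP1 1.41-fold and STAT3 itself 1.23-fold, from 97.1 ± 2.12 to 79.0 ± 1.19 CPM. SOCS2, a feedback inhibitor of cytokine signalling, rose 1.53-fold, and HIF1A, BIRC5 and PTPN1 rose 1.24-, 1.17- and 1.16-fold. SOCS3, a feedback gene chosen after its values were seen, was at 8.81 ± 0.586 and 8.75 ± 0.971 CPM (adjusted p = 0.871). Camera placed the list below other genes (median log2 fold change -0.11, adjusted p = 0.010, or adjusted p = 0.429 with an estimated correlation). The call also ended when GC content and length trends were removed (adjusted p = 0.266, median -0.042).

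Transcripts of the extracellular matrix and of cell adhesion were lower on balance: 21 of 36 tested fell and 7 rose (22 and 7 adjusted over the list alone). Ordered by adjusted p, COL3A1 led the falls, followed by FN1, which encodes fibronectin (110.8 ± 5.62 to 52.7 ± 0.355 CPM, 2.10-fold lower), the basement membrane collagen COL4A5 (2.62-fold lower) and COL5A1 (1.51-fold lower). Rising members were LUM, the laminin chains LAMB1 (3.44-fold, from 0.512 ± 0.0407 CPM) and LAMA3 (1.35-fold), and the integrin ITGB4 (1.30-fold). Of 19 tested mesenchymal and epithelial-mesenchymal transition genes 10 fell and 1 rose, TGFBI, with the same counts adjusted over the list alone. The growth factor TGFB1 fell from 101.3 ± 3.76 to 62.9 ± 2.80 CPM and the cadherin CDH11 1.78-fold. Of 19 tested genes tied to bone metastasis and bone resorption 11 fell and none rose (12 and 1 adjusted over the list alone). They included TNFRSF11B, which encodes the decoy receptor osteoprotegerin that restrains bone resorption (6.41 ± 0.594 to 2.58 ± 0.159 CPM, 2.5-fold lower), and the osteoblast factor RUNX2 (1.23-fold lower). Camera placed the matrix list (median log2 fold change -0.21, adjusted p = 0.000407), the mesenchymal list (-0.28, adjusted p = 0.0017) and the bone list (-0.42, adjusted p = 0.000407) below other genes, each with an adjusted p = 0.117 under an estimated correlation. The mesenchymal call also ended when members shared with other lists were left out (adjusted p = 0.187), and without LIFR shRNA replicate 3 the count was 3 higher and 9 lower in that list and 1 higher and 9 lower in the bone list. The medians lay nearer 0 over the genes that DESeq2 fitted (-0.134 mesenchymal, -0.23 bone) and with no filter on low counts (-0.128 and -0.199).

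Lists of cell identity and of dormancy held changed genes that moved both ways, and none of them passed camera. Against 32.3% of all tested genes, the share called was 76.9% for dormancy-associated genes, 75.7% for estrogen receptor targets and 69.2% for luminal markers. It was 52.2% for Hippo-YAP targets, and nearer the share of all genes for basal (41.2%) and stem cell (37.5%) markers. These shares were not compared at matched abundance, and small changes are called more readily in abundant genes. With at least 1 CPM required in 3 libraries, 5500 of 14370 genes were called. A share above 32.3% therefore does not by itself set a list apart. Of 26 tested dormancy-associated genes 12 fell and 8 rose (12 and 9 adjusted over the list alone, camera adjusted p = 0.479). BMP7, COL4A5, LIFR and THBS1 fell, the last by 1.28-fold, and BHLHE41 (2.75-fold), IGFBP5 (1.24-fold), CTSD (1.21-fold) and QSOX1 (1.18-fold) rose. Of 37 estrogen receptor targets 14 rose and 14 fell (18 and 14 adjusted over the list alone, camera adjusted p = 0.878). STC2 rose 1.53-fold, GREB1 1.36-fold from 606 ± 29 to 824 ± 21.7 CPM and PKIB 1.35-fold, while the trefoil peptide TFF3 fell 2.45-fold and EGR3 1.94-fold. Among 26 luminal markers 8 rose and 10 fell (camera adjusted p = 0.848), with the adhesion molecule CDH1 1.21-fold higher at 1504 ± 16.6 CPM and the transcription factors TFAP2A and FOXA1 1.38- and 1.15-fold lower. Basal markers counted 3 higher and 4 lower of 17 (camera adjusted p = 0.726), with CAV2 1.32-fold higher and TP63 2.27-fold lower. Stem cell markers counted 2 higher and 4 lower of 16 (camera adjusted p = 0.543). The pluripotency factor SOX2 fell from 49.6 ± 1.55 to 18.1 ± 0.219 CPM (2.73-fold lower) and the receptor NOTCH1 1.35-fold, while CD44 and ABCG2 rose 1.19- and 1.39-fold. Hippo-YAP targets counted 4 higher and 8 lower of 23 (camera adjusted p = 0.523), with AMOTL1 1.81-fold higher and IGFBP3 1.63-fold lower. ASAP1 in that list was 1.29-fold lower and lies in a stretch of chromosome 8 in which most genes were lower. Luminal, basal, stem cell and Hippo-YAP counts were the same adjusted over the list alone.

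Of 25 cholesterol biosynthesis genes 9 fell, 1 rose and 15 did not pass (12 and 1 adjusted over the list alone). DHCR7 fell 1.2-fold, HMGCS1 1.15-fold and SQLE 1.11-fold, and FDFT1 rose 1.08-fold. Camera passed the list (median log2 fold change -0.06, adjusted p = 0.0144, or adjusted p = 0.623 with an estimated correlation). Its call ended without control replicate 2 (adjusted p = 0.0586), without LIFR shRNA replicate 3 (0.0519) and after GC content and length trends were removed (0.142), where the median was -0.062.

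The remaining lists did not pass camera. Cell cycle genes counted 10 higher and 7 lower of 42 (11 and 8 adjusted over the list alone, camera adjusted p = 0.848), with TK1 1.29-fold and RRM2 1.2-fold higher and CCND1 1.17-fold lower. Of 28 p53 targets 7 rose and 8 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.889), among them GDF15, 1.59-fold lower, and CDKN1A, 1.18-fold lower. Hypoxia and glycolysis genes counted 8 higher and 8 lower of 31 (9 and 8 adjusted over the list alone, camera adjusted p = 0.726). The glucose transporter SLC2A1 rose 1.36-fold and hexokinase HK2 1.37-fold, while ANGPTL4 fell 1.72-fold and VEGFA 1.19-fold. Of 28 genes of the unfolded protein and ATF4 response 4 rose and 8 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.165), including the cystine transporter SLC7A11 (1.91-fold lower) and the serine synthesis enzyme PHGDH (66.5 ± 1.03 to 41.1 ± 0.993 CPM, 1.62-fold lower). Interferon and double-stranded RNA response genes counted 4 higher and 7 lower of 33 (the same adjusted over the list alone, camera adjusted p = 0.479), with SAMD9 3.71-fold higher and BST2 2.80-fold lower. The higher members numbered 2 without control replicate 2, where IFIH1 (adjusted p = 0.0606) and STAT2 (0.173) did not pass, and 1 by DESeq2 or after thinning to the smallest library total. NF-kB genes counted 4 higher and 7 lower of 24 (4 and 8 adjusted over the list alone, camera adjusted p = 0.72), with BIRC3 1.39-fold higher and CSF1 1.62-fold lower. The lower members numbered 4 without control replicate 2 or control replicate 3, 3 without LIFR shRNA replicate 3 and 3 by DESeq2.

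Markers of other cell types were few among the genes tested. Of 18 fibroblast markers 7 were tested, 2 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.726), and LUM and COL3A1, named above, went opposite ways. Of 20 leukocyte markers 4 were tested, too few for camera, and only ITGAM passed, lower with LIFR shRNA (3.42 ± 0.0982 to 2.71 ± 0.517 CPM, adjusted p = 0.0266, and the same adjusted over the list alone). That call ended without control replicates 1 or 2 (adjusted p = 0.0626 and 0.0756) or LIFR shRNA replicates 2 or 3 (0.0558 and 0.263) and by DESeq2 (0.173), and 1 other member was called higher without control replicate 2. None of 13 mitochondrially encoded genes passed edgeR over all genes or adjusted over the list alone (0 also at an unadjusted p under 0.05 and 0 by DESeq2, camera adjusted p = 0.994). MT-ND4 was at 5078 ± 713 and 4882 ± 389 CPM, and MT-CO1 at 4220 ± 445 and 4230 ± 262 CPM. Of 23 replication-dependent histone genes 2 rose (1 adjusted over the list alone, camera adjusted p = 0.726). HIST1H1D was 1.26-fold higher and did not pass without control replicate 2 (adjusted p = 0.089) or LIFR shRNA replicate 3 (0.169), or by DESeq2 (0.091), and HIST1H1C was 1.07-fold higher and did not pass without control replicates 2 or 3 (0.0719 and 0.221) or LIFR shRNA replicates 1 or 3 (0.135 and 0.124), nor in 7 other alternatives (adjusted p 0.0512 to 0.203). Without control replicate 1, 1 histone gene was called lower.

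Over the 22 lists tested, camera called 7, all lower with LIFR shRNA, and called 0 with an estimated correlation (5 at an unadjusted p under 0.05). By fry, 12 lists moved on balance in 1 direction, all of them lower, and 20 held genes that changed in either direction. The exceptions to the latter were the mitochondrial and histone lists. Fry does not compare a list with other genes, and 32.3% of all tested genes changed. Passing it in either direction therefore does not set a list apart: the interferon list passed with 33.3% of its members called. Median, mean and camera direction differed in sign for estrogen receptor targets (median 0.01 and up, mean -0.06), hypoxia genes (median 0.04 and up, mean -0.02), fibroblast markers (median -0.12 and down, mean 0.01) and mitochondrial genes (median 0.003, mean -0.002 and down). These medians moved with single libraries. The fibroblast median was 0.103 without control replicate 1, -0.067 without control replicate 2, -0.194 without control replicate 3 and -0.062 without LIFR shRNA replicate 3. With 1 library left out, the estrogen receptor median ranged from -0.008 (without control replicate 1) to 0.038 (without LIFR shRNA replicate 2), the mitochondrial median from -0.048 (without control replicate 2) to 0.093 (without control replicate 1) and the hypoxia median from 0.018 (without control replicate 3) to 0.047 (without control replicate 2).

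**Figure D3:**
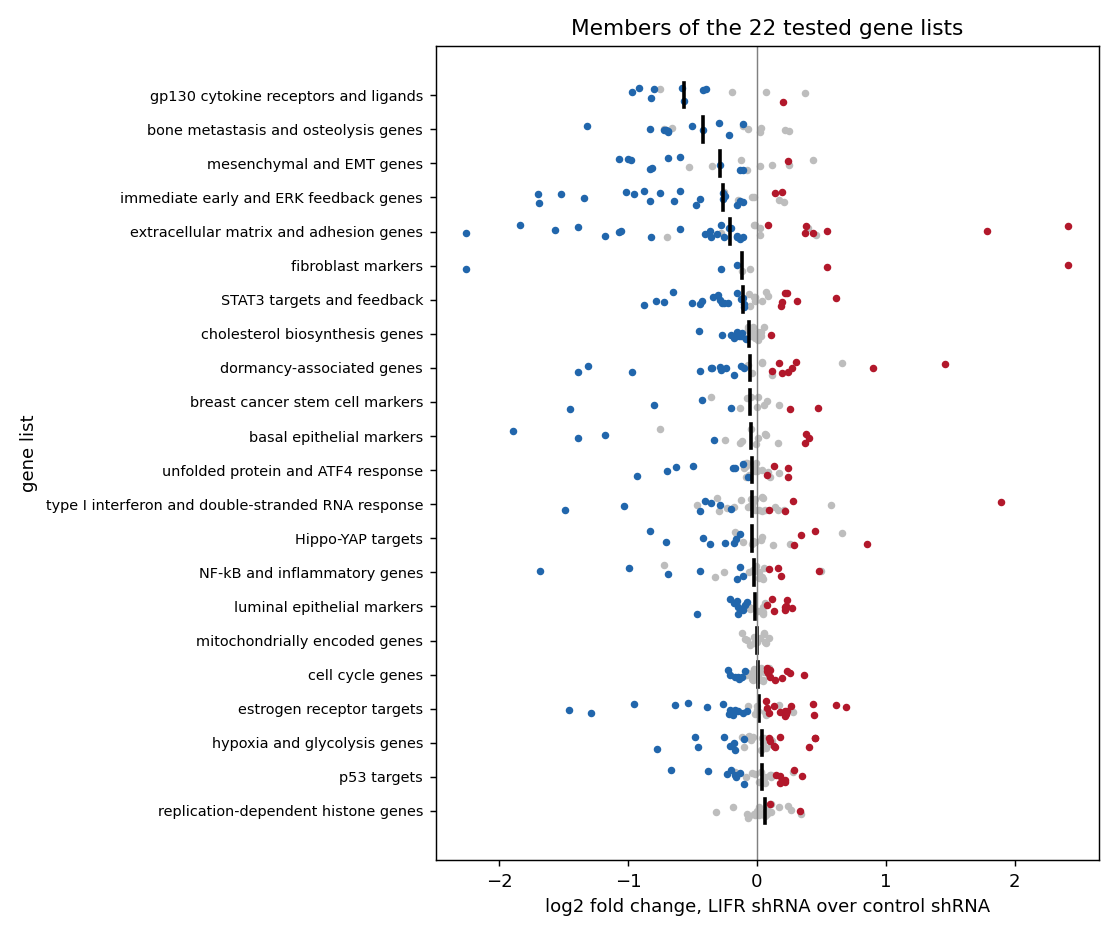
Log2 fold change of LIFR shRNA over control shRNA (x axis) for each tested member of 22 gene lists (rows, ordered by median), with called members in red where higher and blue where lower, uncalled members in grey, and the median as a black bar; points are spread vertically only to separate them. The gp130 list has the lowest median (-0.57), with 8 of its 13 members called lower.

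The authors' deposited table of this comparison covers 36271 genes. Of these, 5230 pass in edgeR in the authors' deposited table, 4068 in DESeq2 and 790 in baySeq, and 734 pass in all 3. Of the 5687 genes called here, 4894 (86.1%) also pass by edgeR in the authors' deposited table, all 4894 in the same direction. The log2 fold changes fitted here and the edgeR values of the authors' deposited table had a Pearson r of 0.99995 across genes, which are not independent replicates.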

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

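Thinning to the smallest library total and removal of GC content and length trends were chosen after the data were seen, and the other alternatives before. LIFR was called lower in each alternative run. Genes changed numbered 4004 with DESeq2 and 4882 to 5369 with 1 library left out, against 5687, and the share of calls that were higher stayed between 46.2 and 51.8%. DESeq2 called 1902 genes higher against 2857, the cause of which was not tested, and the stricter filter of at least 1 CPM in 3 libraries left 201 genes changed at least 2-fold against 373, which follows from the fewer genes tested (14370). Lists past camera went from 7 to 0 with an estimated correlation. The estimate was -0.029 for the gp130 list and -0.038 for the mesenchymal list, under the preset 0.01. For these lists that argues against a correlation above the preset as the cause. The bone (0.012) and matrix (0.018) lists lay just above the preset. The remaining called lists lay between 0.063 (STAT3) and 0.162 (cholesterol), and there a higher correlation stays open. The estimated setting also takes far fewer degrees of freedom, from the 6 libraries rather than the genes, which raises p at any correlation. For the gp130 list the unadjusted camera p went from 0.000102 to 0.0147 although its estimate was under the preset. How much each difference contributed to ending the calls was not tested. Other counts over all genes stayed within 1.5 times the reported ones. Of 782 counts of higher or lower list members, 34 in 8 lists did not, each by at most 4 genes; 15 of these came from leaving out 1 library. They include 2 cholesterol genes higher against 1 after removal of GC content and length trends, and 1 bone gene higher against 0 with the replicate block, after thinning or after that removal. With the replicate number as a block (replicate block), 5850 genes changed. Deviations of same-numbered libraries from their group means correlated at 0.017, 0.043 and 0.038, and those of differently numbered libraries at 0.012 or less. Each library thus correlated best with its own number in the other group, which is a hint of pairing from the data and not from the design. Correlations this small do not decide whether the replicates were paired, and the main fit took them as unpaired. Over 162 named genes, 2666 of 2748 alternative values kept direction and side of the threshold, 11 uncalled values changed sign, 68 lost the call, 3 gained a call and 0 called values reversed. For the lists, 367 of 395 values kept both, 16 uncalled values in 6 lists changed sign and 12 lost the call. Camera was not run for the DESeq2 and non-robust settings, which do not enter its values. Depth limits low genes most: CNTFR, CNTF and IL11RA lay at or under about 1 CPM.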

Other observations

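Gene families, formed by the letters that begin a symbol, and the genes of the next paragraph were chosen after the data were seen, as were all tests below except those of the splits, of copy number for 2-fold genes and of the windows of neighbouring genes. Of 159 families with at least 10 tested members, camera placed 2 below other genes. In the COL family 16 of 29 fell and 4 rose (median log2 fold change -0.28, adjusted p = 0.00971, or adjusted p = 0.935 with an estimated correlation). Besides COL3A1, COL4A5 and COL5A1, the falls included the type VI collagen chains COL6A1 (20.2 to 8.90 CPM) and COL6A2 (30.8 to 17.4 CPM) and the fibril-associated COL14A1 (3.11 to 0.471 CPM). Of the type VI chains also tested, COL6A3 did not pass (log2 fold change -0.20, adjusted p = 0.335) and the scarce COL6A6 rose from 0.157 to 0.484 CPM, while COL9A2 rose from 7.47 to 9.29 CPM. COL4A3BP, which rose from 59.6 to 66.8 CPM, is counted by its name only and is not a collagen. In the SOX family of transcription factors 6 of 11 fell and 0 rose (median -0.21, adjusted p = 0.0387, or adjusted p = 0.935 with an estimated correlation): SOX2, SOX9 (25.5 to 18.7 CPM), SOX13, SOX12 and the scarce SOX8 and SOX21. The COL family stayed called across 3 other scalings and with each library left out (adjusted p 0.0025 to 0.0302), whereas the SOX family was lost without control replicate 2 (0.0566), control replicate 3 (0.148) or LIFR shRNA replicate 3 (0.0708).

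HAPLN1, which encodes a link protein that ties proteoglycans to hyaluronan, had 0 counts in each of the 3 control libraries and 86, 95 and 139 counts in LIFR shRNA replicates 1 to 3. Against a floor of 3 counts over the control group it was at least 89.9-fold higher, and it was the 1 gene with 0 counts in a whole group and at least 10 in every library of the other. HAS2, a hyaluronan synthase, went the other way and fell from 0.936 ± 0.153 to 0.0985 ± 0.0458 CPM (edgeR adjusted p = 3.58e-09). HAS2-AS1 overlaps HAS2 on the opposite strand and was lower too (log2 fold change -1.73), and the assignment of reads within the pair is uncertain.

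The breadth of the response was set beside other splits of the libraries and weighed against technical causes. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 5687 genes, and the highest of the others called 0 (344 at an unadjusted p under 0.05 by edgeR). Every other split mixes both groups, so the group difference widens the spread within each side and few calls were to be expected. The splits therefore cannot tell the response from chance. Of the genes changed at least 2-fold, 87.9% kept call and fold after thinning to the smallest total and 91.2% after removal of GC content and length trends, which argues against depth or composition as the whole cause. After subtraction of the median of the 30 neighbouring genes 90.9% kept the fold, which argues against broad copy number changes as the cause of most of them. Focal changes that cover only a minority of those neighbours would not move the median, and stay open. An effect of the knockdown and a standing difference between the cell populations that carried the hairpins both stay open, since the design ties them together. Direct effects of the hairpins on transcripts other than LIFR could not be examined and stay open too.

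Runs of neighbouring genes shifted together on 2 chromosomes: 57 windows of 31 genes had a median beyond 0.306, the largest in 1000 permuted gene orders, and in the more uniform region 90.5% of genes moved the same way. On chromosome 8 the 128 tested genes from 129.8 Mb to the last one at 145.1 Mb had a median log2 fold change of -0.27 (-0.30 to -0.26 with 1 library left out; 86 called lower, 2 higher), against 0 for the 484 genes before it. Beyond the region that the windows defined, 97.7% of the 44 remaining genes were lower; after removal of GC content and length trends the median was -0.207 with a standard error of 0.028 over all 128 genes and -0.171 with a standard error of 0.031 over those 44, so a partial loss of distal 8q in the LIFR shRNA cells, or a gain in the controls, is a candidate explanation and composition is not the whole cause. On chromosome 5 the region spanned 140.8 to 141.5 Mb. In it or within 1 Mb either side, 23 of 53 protocadherin genes were called higher and 4 lower. Over the same span, 29 protein-coding genes of other families had a median of 0.028 with a standard error of 0.063 (7 called higher, 1 lower). That argues against a gain that raised all of them by 0.2 or more on the log2 scale. Standard errors in this paragraph treat genes as independent. Reads shared between the protocadherin genes stay open, since the PCDHB genes, which share no constant exons, had a median of 0.343 with a standard error of 0.123 but helped to define the region (camera adjusted p = 0.0574 as a family); a change in regulation of the cluster or a gain limited to it was not tested, and DNA was not measured; the chromosome 8 stretch and the protocadherin genes together held 115 of the changed genes (2.02%).

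The lower immediate early and ERK feedback genes did not rest on 1 library, since 18 of the 19 members called lower were also called lower whichever was left out. A smaller share of cycling cells with LIFR shRNA is argued against by the cell cycle genes. Their median log2 fold change was 0.01, and -0.011 to 0.017 with 1 library left out. The standard error of 0.023 treats these genes as independent, although their estimated correlation was 0.113. Handling at harvest would act first on rapidly induced members, and cannot be told apart here. The 13 rapidly induced members had a median of -0.25 and the 12 slower ones a median of -0.70. The difference in means (-0.251, slower minus rapid) had a 2-sided permutation p of 0.278, from shuffling genes, which are not replicates. Lower ERK pathway output with LIFR shRNA is left as a hypothesis for this group, and no phosphoprotein was measured.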
